A study of Zea mays with 48 samples.

How the data were processed

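The series comprises 48 2-colour microarray hybridisations of maize RNA from embryos and endosperm isolated 6 days after pollination. Per the labels, the plants were the inbred lines UH301, UH005 and UH250 and the reciprocal hybrids of UH301 with each of the other lines. Selfed and crossed ears of a set were pollinated on the same day. Nucellus pieces with the embryo sac were dissected out, the endosperm was lifted out with tweezers, and embryos were freed from it with glass needles. Per the labels' protocols, mRNA was bound to oligo-dT beads, amplified as cDNA by template switching and long-distance PCR with a cycle number set for each sample, and labelled with Cy3 or Cy5 through random primers. Amplification before labelling can change ratios between transcripts. How large that effect was is not given in the sources used here.

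The deposited table holds 1 log ratio per probe and array, taken here as log2 values that the authors made from the 2 channels. The log base, the background correction and the normalization method are not given in the sources used here. Array medians lay between -0.20 and 0.11, so the deposited values were used without further centring. The table has 3592 entries, of which 7 control entries were left out and 3585 probes kept. An array had values for 931 to 3436 of them, and 377 probes had a value on all 48 arrays. The probes whose IDs begin with P_ (the P set) had no value on 10 arrays, all from cross 301/005 (replicates 1 and 2 of embryo and replicate 2 of endosperm). No signal intensities were used, so the signal behind a ratio is unknown, and the number of arrays limits the precision.

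The direction of the ratio is not stated in the labels. It was taken as channel 1 over channel 2, which is likely, because the titles name the RNAs in that order. A second basis was chosen after the data had been looked at in several size classes. Under this direction, probes whose inbred lines differed by over 1 on the log2 scale lay above the mid-parent for 35 of 53, 110 of 127, 16 of 22 and 20 of 25 probes in the 301/005 embryo, 301/005 endosperm, 301/250 embryo and 301/250 endosperm, against 48.5%, 45.4%, 46.3% and 45.3% of all probes. That is where hybrids lie on a log scale if they are near the mean of the linear parental values. Because the direction rests partly on it, the sign of the mid-parent difference for such probes is not used as a result. If the direction were the other way, every log2 difference in the text would change sign, while seed-parent shares and correlations between contrasts would not. Odd-numbered replicates carried the inbred RNA in channel 1 (Cy3) and even-numbered ones the hybrid RNA, and all ratios were turned to hybrid over inbred. After turning, the inbred difference of each 301/005 endosperm replicate correlated across probes with that of the other replicates at r 0.41 to 0.64. Probes are not independent replicates. The first-named line of a cross is taken as its seed parent, by convention.

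Samples were grouped by cross, tissue and replicate number from the array titles. The 4 arrays of 1 replicate form a loop, in which both reciprocal hybrids were each hybridised against both inbred lines. Cross 301/005 has 4 loops per tissue and cross 301/250 has 2. The labels call the loops biological replicates. Arrays of a loop share RNAs, and the labels state a shared pollination day, so the loop and not the array was the unit of replication. Each loop gave, per probe, the mean of the hybrids minus the mean of the inbreds (mid-parent difference), the 301-seeded minus the other hybrid (reciprocal difference), and inbred 301 minus the other inbred (inbred difference). A constant dye effect cancels in the last 2 of these. A dye coefficient common to all loops was fitted for the first. A probe was tested in a cross and tissue if at least 2 loops, with both dye orientations, had a value and at least 3 residual degrees of freedom remained. These limits were set after the table had been seen.

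The 12 loops were fitted together with 1 coefficient per cross and tissue, least squares per pattern of missing loops, and the moderated variances of limma 3.58.1 in R 4.3.3. P-values are two-sided and were adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05. On the 377 probes without gaps the p-values differed from those of limma's lmFit and eBayes by at most 4.4e-16. Every adjusted p in the text is from this limma fit unless a sentence names another test. Errors given as SE come from the same fit, and n counts loops. A hybrid lay outside both inbreds if it differed from each of them in 1 direction and the larger p-value passed the adjustment. The main comparisons, most alternatives and the rule for named genes were fixed before the data were examined. The comparison of each hybrid with each single inbred, the loop closure check, the seed-parent share with its tests, the chromatin gene families and the tests of gene lists against probes of the P set were added after values had been seen. So were the fits within 1 array version, the list tests after scaling and over all comparisons, and every alternative for hybrids against single inbreds.

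The procedure was tested on simulated data with known changes. Many probes were changed at once: in 301/005 embryos 55, 55 and 57 of 1752 tested probes by 0.5, 1 and 2 for the mid-parent difference. That eases the adjustment over all probes, so a change in only a few probes would be recovered less often than given here. The simulated noise of a probe had the same spread in all groups, so the percentages do not measure the power of each group under its own spread. At a simulated log2 change of 1 the procedure recovered 80.0%, 83.9%, 86.0% and 73.1% of changed probes for the mid-parent difference in the 301/005 embryo, 301/005 endosperm, 301/250 embryo and 301/250 endosperm. At a change of 0.5, larger than most of the mid-parent values of named genes, it recovered 47.3%, 40.7%, 37.3% and 15.4%, so smaller changes can be missed. In the same order 9 of 135, 6 of 129, 3 of 126 and 3 of 99 calls over all sizes were false. For the reciprocal difference a change of 1 was recovered in 66.7%, 67.2%, 44.4% and 67.2%, and for the inbred difference in 66.7%, 58.3%, 47.6% and 48.3%. At 0.5 these shares were 29.3%, 25.0%, 10.9% and 12.3%, and 15.0%, 21.3%, 6.25% and 3.12%. Each loop also gives a closure value, the difference between 2 routes to the same contrast, which should be 0 without array error. The limma fit found 0 probes with a closure value apart from 0 in each of the 4 groups, with 102, 114, 103 and 13 probes at an unadjusted p under 0.05. Closure values spread less in 301/250 endosperm (SD over probes 0.29 and 0.28 in its loops) than in the other loops (0.38 to 0.68). As the fit shares 1 spread per probe over all groups, p-values in 301/250 endosperm are likely too large and those in noisier groups can be too small. Counts of called probes are therefore not comparable between groups.

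Probe IDs were named by exact match of the ID, without its prefix, to symbols and synonyms of the RefSeq gene table. This gave names to 62 probes of 59 genes. A further 1 ID matched several genes, and 2 matching IDs are words that can mean more than 1 gene. These were left unnamed and are counted among the 3523 IDs without a name, of which the others had no match. Most other probes carry clone or plate numbers and are given by ID. P, S and V before a name mark different probe sets, and several probes can stand for 1 gene: probes named MET1 and DMT101 match the same gene. Named genes were chosen by a fixed rule. For each comparison it takes the largest changes in each direction among named genes past the threshold, with the same sign in every loop. Where none passed, it takes the 3 with the smallest p in each direction, as values, and at most 2 unnamed probes per direction past the threshold. Members of the imprinted list are given whether or not they pass.

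Of 27 gene lists fixed beforehand, 8 had a named probe. The list for histones and chromatin had 17 probes (histone deacetylases, nucleosome assembly factors, SET-domain proteins, DNA methyltransferases and a remodelling factor, with no core histone). The imprinted list had 9, of which at most 3 were measured in a comparison (FIE2 and the DNA methyltransferases DMT101 and DMT106, which its name pattern also takes). WEE1, EF1A, HSP101, GLN4 and MEG1 were the only members of their lists (cell cycle, translation, chaperones, amino acid metabolism and basal transfer layer), and MEG1 was tested in no comparison. Where a list had 1 measured member, passing when adjusted over the list alone means only an unadjusted p under 0.05. No probe was named for nucellus and pericarp, zeins, starch metabolism, aleurone or the region around the embryo, so the purity of the dissected tissues was not measured. Lists with at least 5 measured members were tested with limma's camera on moderated statistics with a preset correlation of 0.01. An alternative used the mean residual correlation of member pairs, floored at 0, which is not camera's own estimator. As 1 list could be tested in each of the 12 comparisons, its adjusted p within a comparison equals its p. Adjusted over the 12 comparisons, none passed.

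Alternatives tried were arrays centred on their medians, arrays also scaled to 1 spread, only probes on all arrays, a spread estimated from the compared loops alone, fits of single arrays with and without the loop as a block, a robust variance prior, no dye coefficient or 1 per tissue, a linear mid-parent, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.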

Results

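Gene expression was compared between maize hybrids and their inbred parents in embryos and in endosperm, the nutritive tissue of the kernel, 6 days after pollination. The series title names heterosis, the better performance of hybrids than of their parents, as the subject. The log ratios used here measure expression and not performance. Inbred line UH301 was crossed in both directions with UH005 and with UH250, and hybrids are written with the seed parent first (301x005, 005x301, 301x250, 250x301). The 48 arrays form 12 loops of 4 arrays, with 4 loops per tissue for cross 301/005 and 2 per tissue for cross 301/250. No array held embryo beside endosperm RNA, so levels of the tissues were not compared, only differences within each. Of 3585 probes, 62 could be named, mainly for chromatin genes. Values are log2 differences with the likely direction of the ratio, which the labels do not state.

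In embryos of cross 301/005 no named gene lay far enough from the mid-parent, the mean of both inbreds, to pass the test. WEE1, a kinase that delays entry into mitosis, had the lowest p among genes below it, at -0.43 ± 0.13 (SE, n = 3 loops), with 3 of 3 loops below 0 and a limma adjusted p of 0.618. NFD106, a high mobility group factor, measured -0.24 ± 0.12 (SE, n = 2). GLN4, a glutamine synthetase, measured 0.45 ± 0.37 (SE, n = 3) and NFA103, a nucleosome assembly factor, 0.19 ± 0.12 (SE, n = 2). DMT106 (0.09 ± 0.10 SE) and the glycolytic gene GAPDH (-0.11 ± 0.13 SE) lay within 1 standard error of the mid-parent, and the imprinted list's other member, DMT101, measured -0.08 ± 0.16. WEE1, the single member of the cell cycle list, was the 1 gene past the threshold when adjusted over the list alone, which here is its unadjusted limma p of 0.0095. The histones and chromatin list had 5 of 6 measured members above the mid-parent with a median of 0.07, which camera did not separate from other probes (adjusted p = 0.206). Over all 1752 probes tested limma called 0, with 129 at an unadjusted p under 0.05, and fits of single arrays called 1 with the loop as a block and 17 without it.

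In endosperm of the same cross the gene with the lowest p was FIE2, a Polycomb group gene. Its mid-parent difference was -0.76 ± 0.15 (SE, n = 3 loops), with 3 of 3 loops below 0, and it did not pass over all probes (limma adjusted p = 0.571). It was the 1 of 3 measured members of the imprinted list past the threshold adjusted over the list alone, beside DMT106 at -0.11 ± 0.08 and DMT101 at 0.01 ± 0.20. GTE102, a bromodomain gene, measured -0.43 ± 0.13 (SE, n = 3) and NFD106 -0.25 ± 0.10 (SE, n = 3), each below 0 in 3 of 3 loops. Above the mid-parent, the DNA methyltransferase gene MET1 measured 0.41 ± 0.22, NFA102 0.21 ± 0.14 and GAPDH 0.12 ± 0.11. DMT101 is another probe of the MET1 gene and had no value in replicate 1, where MET1 measured 1.03. Members of the histones and chromatin list were below the mid-parent in 6 of 9 cases (median -0.05, adjusted p = 0.648). Limma called 0 of 2076 probes, with 160 at an unadjusted p under 0.05. The fits of single arrays called 3 with the block and 28 without, and a spread estimated from these loops alone gave 1.

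In embryos of cross 301/250, FIE2 measured -0.54 ± 0.18 (SE, n = 2 loops) with both loops below 0, NFA102 -0.40 ± 0.16 and the bromodomain gene BRD103 -0.27 ± 0.15. NFE101 at 0.14 ± 0.18, NFC103 at 0.10 ± 0.16 and NFD101 at 0.03 ± 0.12 were the genes above the mid-parent with the lowest p. The 7 measured genes of the histones and chromatin list were all below it, with a median of -0.11 and an adjusted p of 0.0489. That call was lost with an estimated correlation (adjusted p = 0.164), after centring (adjusted p = 0.0502), after scaling (adjusted p = 0.0745) and against other probes of the P set (adjusted p = 0.266). FIE2 was the single imprinted list member measured and passed adjusted over the list alone. In endosperm, NFD106 measured -0.18 ± 0.12, NFE101 -0.25 ± 0.18, WEE1 -0.17 ± 0.15, the deacetylase gene HDT102 0.15 ± 0.14, GAPDH 0.10 ± 0.16 and NFC103 0.07 ± 0.16 (SE, n = 2). The imprinted list members present there were DMT101 (-0.16 ± 0.20) and DMT106 (-0.04 ± 0.12) and FIE2 (0.04 ± 0.18). Limma called 0 of 1460 probes in embryos and 0 of 1890 in endosperm, with 94 and 23 at an unadjusted p under 0.05. Without the loop block the fit of single arrays called 0 and 1.

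**Figure D1:**
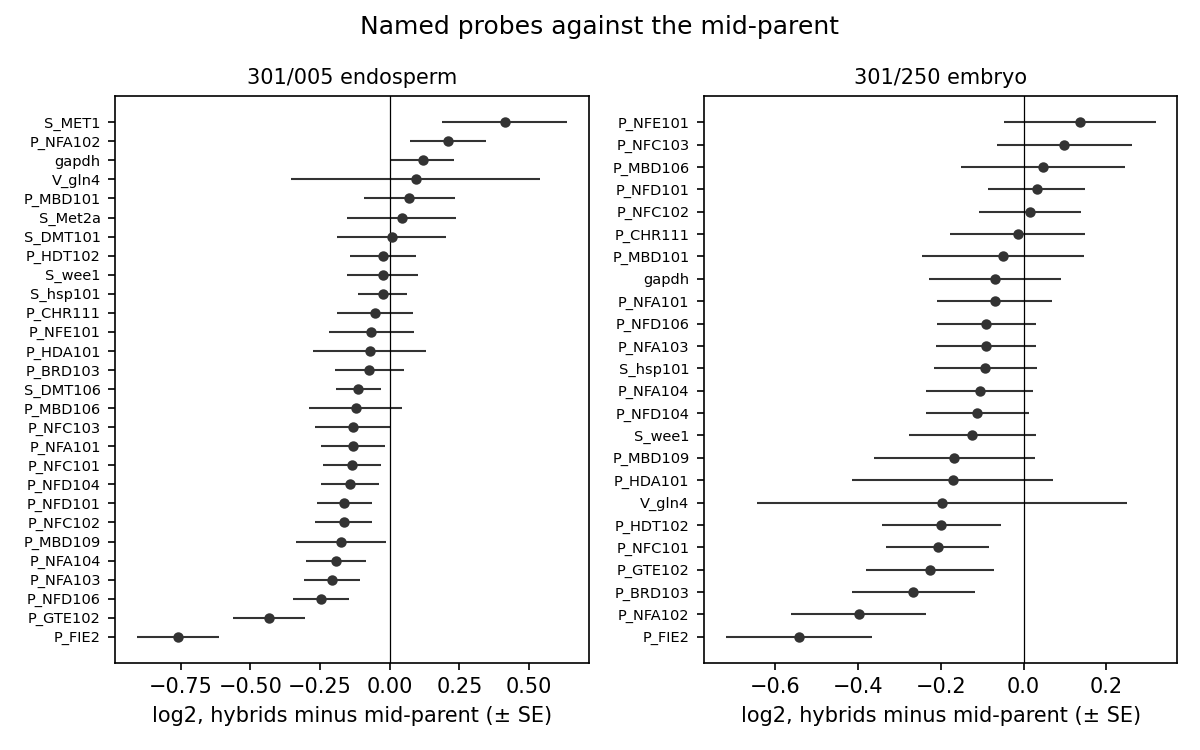
Mid-parent difference (log2, hybrids minus mean of inbreds, ± SE) of named probes in 301/005 endosperm and 301/250 embryos. FIE2 lies lowest in both groups, at -0.76 and -0.54, and no probe passed the limma threshold over all probes.

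The strict form of non-additive expression, a hybrid above or below both inbreds, was found for no probe. In 301/005 embryos the nearest named genes were HDA113, a histone deacetylase gene, which in 301x005 exceeded inbred 301 by 0.76 and inbred 005 by 1.14, and WEE1, which in 005x301 measured -0.49 against 301 and -0.65 against 005. In 301/005 endosperm MET1 in 301x005 measured 0.61 and 0.76 against the 2 inbreds, and NFC101 -0.26 and -0.33. In 301/250 embryos HDA113 in 250x301 measured 0.91 and 0.63, and FIE2 in 301x250 -0.78 and -0.53. In 301/250 endosperm HDA113 in 250x301 measured 0.94 and 0.45. Each of these has a limma adjusted p of 1. Limma called 0 of 2621, 2878, 2445 and 2654 probes in the 301/005 embryo, 301/005 endosperm, 301/250 embryo and 301/250 endosperm. At an unadjusted p under 0.05 there were 34, 30, 18 and 4.

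Reciprocal hybrids carry the same parental genomes with the seed and pollen parent exchanged. As endosperm receives 2 maternal genomes to 1 paternal, such hybrids also differ there in the dosage of the parental genomes. In 301/005 endosperm they differed at 37 of 2351 probes, of which 36 were higher in 301x005 and 1 in 005x301. The called probes are unnamed. KH7 was higher in 301x005 by 2.81 ± 0.26 (SE, 2 of 2 loops, limma adjusted p = 0.0142) and KA10 by 2.17 ± 0.33 (SE, 3 of 3 loops, limma adjusted p = 0.0334), and AC2 measured -0.64 ± 0.13 (SE, 4 of 4 loops, limma adjusted p = 0.0487). Among named genes MET1 measured 0.78 ± 0.21 (SE, 3 of 3 loops above 0, limma adjusted p = 0.164), while DMT101, the other probe of that gene, gave 0.08 ± 0.26. The deacetylase gene HDA101 measured 0.64 ± 0.27, and 0.22 without replicate 1, and BRD103 0.45 ± 0.21, with 2 of 3 loops above 0. On the other side GLN4 measured -0.89 ± 0.25 (SE, n = 2 loops), past the threshold adjusted over its list alone, where it is the single member, FIE2 -0.53 ± 0.22 and NFC101 -0.31 ± 0.14. DMT106 of the imprinted list measured 0.13 ± 0.14. The histones and chromatin list had 6 of 9 members above 0 (median 0.07, adjusted p = 0.148). For the imprinted list the median was 0.08 and the mean -0.10, opposite in sign. There were 338 probes at an unadjusted p under 0.05. The count of 37 became 4, 10 and 6 without replicates 1, 3 and 4, and 0 with a spread from these loops alone.

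In 301/005 embryos limma called 0 of 1892 probes for the reciprocal difference, with 117 at an unadjusted p under 0.05, and the fits of single arrays called 6 and 4. NFD106 measured 1.14 ± 0.29 (SE, n = 2 loops), from 0.52 in replicate 3 and 1.77 in replicate 4. The nucleosome assembly factors NFA104 and NFA103 measured 0.73 ± 0.22 and 0.61 ± 0.23 and EF1A, a translation elongation factor, -0.79 ± 0.37. These rest mainly on replicate 4, with 0.36, 0.14 and -0.11 in replicate 3 and 1.11, 1.07 and -1.47 in replicate 4. Smaller values were -0.14 for GAPDH and DMT106 and 0.18 ± 0.21 for DMT101. The 6 measured genes of the histones and chromatin list were all higher in 301x005, with a median of 0.22 and an adjusted p of 0.021. The adjusted p was 0.0345 with an estimated correlation, and 0.0161 and 0.0204 after centring and scaling. Adjusted over all 12 comparisons it was 0.0838. The same probes on the same arrays give the inbred difference, with all 6 below 0, so the list's reciprocal and inbred calls are not separate findings.

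In 301/250 embryos 4 of 1604 probes passed, all higher in 301x250. UF10 was higher by 1.45 ± 0.19 (SE, 2 of 2 loops, limma adjusted p = 0.0161) and S_CC1128 by 1.27 ± 0.19 (SE, 2 of 2 loops, limma adjusted p = 0.0363), and the others, QG10 and UA7, fall outside the naming rule and were named after their values were seen. No named gene passed. NFC103 measured -0.85 ± 0.20 (limma adjusted p = 0.105), MBD113, a methyl-CpG-binding domain gene, -1.08 ± 0.31, from -1.70 and -0.46 in replicates 1 and 2, HDA113 -0.93 ± 0.30, from -1.44 and -0.41, NFE101 0.69 ± 0.23, NFA101 0.41 ± 0.18, GAPDH 0.29 ± 0.17 and FIE2 -0.23 ± 0.27 (SE, n = 2 loops). The histones and chromatin list had 6 of 9 members below 0 (median -0.24, adjusted p = 0.0995). There were 284 probes at an unadjusted p under 0.05. The count of 4 became 10 without replicate 2, and 0 after scaling or with a spread from these loops alone. It became 26 with probes on all arrays and 25 and 8 in the fits of single arrays. In 301/250 endosperm, where the shared spread likely makes p-values too large, limma called 0 of 2177 probes, with 29 at an unadjusted p under 0.05. There MBD106 measured -0.61 ± 0.19, BRD103 -0.36 ± 0.26, HDA113 -0.34 ± 0.30, FIE2 0.30 ± 0.27, MBD109 0.21 ± 0.36, MET1 0.17 ± 0.26, DMT106 0.08 ± 0.20 and DMT101 0.00 ± 0.26. Of the histones and chromatin list 8 of 11 members were below 0 (median -0.10, adjusted p = 0.0495), a call lost with an estimated correlation (adjusted p = 0.0688), after centring (adjusted p = 0.0502) and after scaling (adjusted p = 0.0754). Against other probes of the P set the adjusted p was 0.00608.

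Between the inbred lines of cross 301/005, 151 of 2351 probes passed in endosperm, 108 higher in UH301 and 43 higher in UH005. Groups differ in spread and in number of loops, so this count does not rank them. CE8 was higher in UH301 by 2.61 ± 0.31 (SE, 2 of 2 loops) and BD1 by 2.43 ± 0.40 (SE, 2 of 2 loops), and S_CC30 measured -1.83 ± 0.29 (SE, 2 of 2 loops) and MH10 -1.81 ± 0.19 (SE, 4 of 4 loops). No named gene passed. The heat shock gene HSP101 measured -0.35 ± 0.14 (SE, 3 of 4 loops below 0, limma adjusted p = 0.201) and passed adjusted over its list alone, where it is the single member. HDT102 measured -0.46 ± 0.19, MET2A -0.41 ± 0.21, HDA101 0.47 ± 0.24, FIE2 0.36 ± 0.43, MBD106 0.15 ± 0.22, DMT101 -0.37 ± 0.21 and DMT106 0.00 ± 0.15. The histones and chromatin list had 5 of 9 members below 0 (median -0.33, adjusted p = 0.611). There were 477 probes at an unadjusted p under 0.05. The count of 151 became 82, 82, 67 and 42 without replicates 1, 2, 3 and 4, 55 after scaling, and 0 with a spread from these loops alone.

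In 301/005 embryos 17 of 1892 probes differed between the inbreds, 15 higher in UH301 and 2 in UH005, with 247 at an unadjusted p under 0.05. LE10 was higher in UH301 by 1.35 ± 0.18 (SE, 4 of 4 loops) and AA5 by 1.18 ± 0.18 (SE, 3 of 3 loops), while NG10 measured -1.61 ± 0.25 (SE, 2 of 2 loops) and MH10 -1.51 ± 0.22 (SE, 3 of 3 loops), MH10 with the same sign as in endosperm. GLN4 measured -0.99 ± 0.36 (SE, 3 of 3 loops below 0, limma adjusted p = 0.309) and passed adjusted over its list alone. NFD106 measured -1.02 ± 0.33, from -0.32 and -1.71 in replicates 3 and 4, NFA104 -0.48 ± 0.24, from -0.13 and -0.83, EF1A 0.57 ± 0.45, from -0.44 in replicate 3 and 1.58 in replicate 4, GAPDH 0.26 ± 0.23, HSP101 0.03 ± 0.17, DMT101 -0.24 ± 0.17 and DMT106 0.01 ± 0.17. The 6 measured genes of the histones and chromatin list were all lower in UH301 than in UH005, with a median of -0.31 and an adjusted p of 0.0198, which was 0.0545 with an estimated correlation and 0.0685 after scaling. This comes from the same arrays as the list's reciprocal call and is not separate from it, and NFA103 measured -0.10 in replicate 3 and -0.97 in replicate 4. The count of 17 became 2, 3, 1 and 11 without replicates 1, 2, 3 and 4, 0 with a spread from these loops alone and within either array version, and 101 and 77 in the fits of single arrays. With centred arrays 13 of 18 called probes were higher in UH301, and with scaled arrays 14 of 18.

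UH301 and UH250 differed at 0 probes in limma, of 1604 tested in embryos and 2177 in endosperm, with 119 and 135 at an unadjusted p under 0.05. The fits of single arrays called 11 and 4 in embryos and 5 and 4 in endosperm, with and without the block. In embryos 3 probes passed without replicate 1. There SGB101 measured 1.04 ± 0.57, from 2.30 in replicate 1 and -0.22 in replicate 2, MBD101 0.52 ± 0.28, from 0.95 and 0.09, MBD113 0.62 ± 0.36, GLN4 -0.64 ± 0.44, NFD101 -0.38 ± 0.24, GAPDH -0.30 ± 0.28 and FIE2 0.40 ± 0.53 (SE, n = 2 loops). In endosperm NFE101 measured 0.91 ± 0.28, MBD108 0.84 ± 0.33, from 0.20 and 1.47 in replicates 1 and 2, MBD113 0.53 ± 0.36, from -0.13 and 1.18, the SET-domain gene SDG118 -0.51 ± 0.27, HDA113 -0.45 ± 0.22, DMT101 -0.38 ± 0.21, FIE2 -0.58 ± 0.53 and DMT106 0.14 ± 0.21 (SE, n = 2 loops). The histones and chromatin list was above 0 for 7 of 9 members in embryos (median 0.09, adjusted p = 0.61). In endosperm its 11 members were all lower in UH301, with a median of -0.23 and an adjusted p of 0.0169, which was 0.178 with an estimated correlation, 0.028 after scaling and 0.0372 against other probes of the P set.

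Probes that differed between the UH301 and UH005 inbreds in endosperm also tended to differ between the reciprocal hybrids, in the direction of the seed parent. The lists of 37 and 151 probes shared 22, all higher in UH301 and in 301x005, where independent lists would share 1.65 in that direction. Of the 151 probes 141 had the same sign in both contrasts. Across the 2351 probes Pearson's r was 0.57, against 0.09 in 301/005 embryos, 0.12 in 301/250 embryos and 0.29 in 301/250 endosperm, and probes are not independent replicates. Both contrasts come from the same arrays, and a simulation with each array's noise and no effects gave r of -0.24 on average and -0.18 at most in 100 draws. Over all 3227 probes with values the observed r was 0.40, with a covariance of 0.123 against -0.0377 in the simulation. Taking the contrasts from different loops gave r of 0.33 and 0.36. Over all probes with values in 301/005 embryos r was 0.16, against 0.17 on average in the simulation. In embryo replicates 3 and 4 alone r was -0.055, against 0.065 on average and 0.0014 at the lowest in the simulation.

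The share of the inbred difference kept between the reciprocal hybrids is 0 where the reciprocal hybrids are equal and 1 where they differ as much as their seed parents do. Its sign depends on the convention that the first-named line is the seed parent, which the labels do not state. Estimated per loop with the inbred difference of the other loops as instrument, it was 0.90, 0.39, 0.56 and 0.67 in 301/005 endosperm, a mean of 0.63 ± 0.21 (SD, n = 4 loops). In 301/005 embryos it was -0.29, 0.23, 0.17 and -0.93 (mean -0.20 ± 0.53 SD, n = 4). The instrument was weaker there, with r of 0.31, 0.21, 0.18 and 0.24 between a loop's inbred difference and that of the other loops. In 301/005 endosperm this r was 0.41 to 0.64. The embryo share of -0.93 comes from replicate 4, with 756 probes. The embryo shares are therefore less certain than those of endosperm. The tissues differed by 0.84 in a two-sided exact permutation test (p = 0.0286, the smallest that 4 against 4 loops can give). Shares made with this instrument are not independent, since each uses the inbred differences of the other loops of its group. Their SDs and the p-values of the tests on them are therefore approximate. With same-numbered loops taken as pairs, an added test, exact sign flips gave p = 0.125, the smallest possible with 4 pairs. In 301/250 endosperm the 2 loops gave 0.14 and 0.18, and the crosses differed by 0.47 (exact permutation p = 0.0667, the smallest possible). The form of the estimate matters: a plain slope on each loop's own inbred difference gave 0.33 ± 0.26 in 301/005 endosperm and -0.02 ± 0.45 in embryos (exact permutation p = 0.229). In that form 301/250 embryos had 0.29 and 301/250 endosperm 0.19, so the gap between crosses is smaller and 301/250 embryos lie above 301/250 endosperm. Leaving out values of size 3 or more gave 0.64 ± 0.19 and -0.22 ± 0.51 (exact permutation p = 0.0286). All 3 forms were tried after the data were seen. The test of single probes called 0 for a difference of the reciprocal effect between tissues, and 1 with same-numbered loops as blocks.

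**Figure D2:**
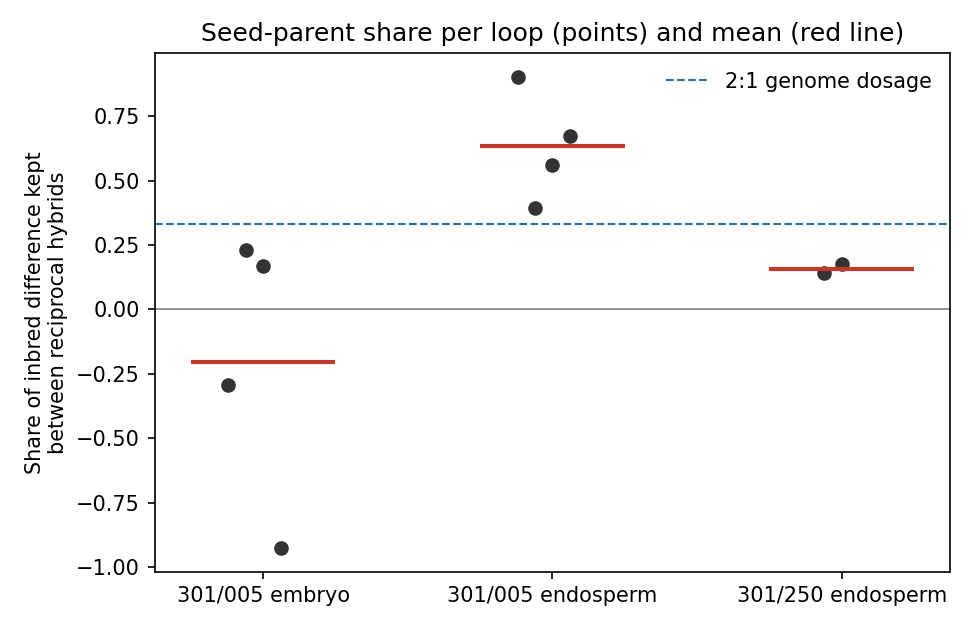
Share of the inbred difference kept between reciprocal hybrids, 1 point per loop, with the mean of each group. The 4 loops of 301/005 endosperm lie between 0.39 and 0.90 and those of 301/005 embryos between -0.93 and 0.23, and 301/250 embryos are omitted because their loops' inbred differences correlate at r = 0.05, too weakly to serve as instrument.

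**Figure D3:**
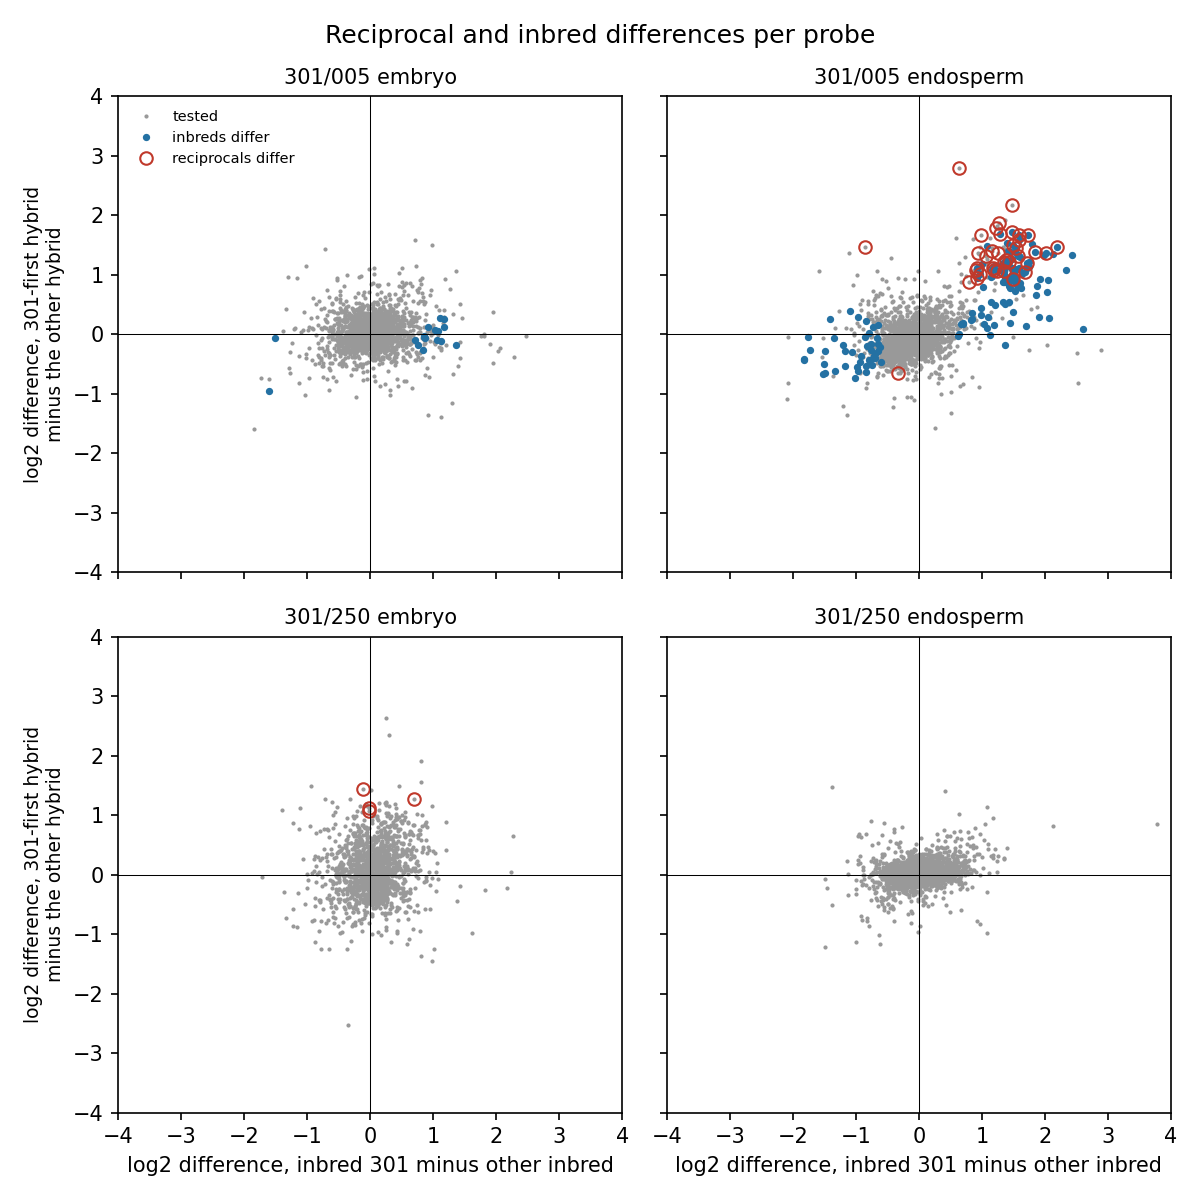
Reciprocal difference against inbred difference (both log2) per probe, 1 panel per cross and tissue. Grey points are tested probes, blue points differ between the inbreds and red circles between the reciprocal hybrids, and in 301/005 endosperm the 22 probes in both lists all lie at positive values.

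Each hybrid was also compared with each single inbred, a comparison added after values had been seen. In this comparison FIE2 was the 1 named gene to pass: in 301/005 endosperm it was lower in 301x005 than in UH005, at -1.45 ± 0.24 (SE, 3 of 3 loops, limma adjusted p = 0.0231). Without replicate 1 it measured -1.39 with an adjusted p of 0.102. The other 3 arrays of each loop do not bear this out: through them the same difference was -0.86, 1.15 and 1.70 in replicates 1, 3 and 4, opposite in sign in 2 of 3 loops, against -1.70, -1.09 and -1.70 directly. The arrays of a loop thus disagree for FIE2, and its values in this tissue, the mid-parent difference included, carry more error than their SE shows. Against UH301 it measured -1.13 ± 0.26 in 005x301 (SE, 3 of 3 loops below 0, limma adjusted p = 0.0692) and -0.34 ± 0.29 in 301x005, with 2 of 4 loops below 0 (-1.84, 0.96, -1.41 and 0.92, split by dye orientation). 005x301 against UH005 measured 0.32 ± 0.24, with 3 of 4 loops above 0. Each endosperm hybrid of this cross differed from its pollen parent at more probes than from its seed parent. This comes from the same arrays as the correlation of the reciprocal with the inbred difference and is not separate from it. 301x005 differed from UH005 at 152 probes, 131 higher and 21 lower, and from UH301 at 0. 005x301 differed from UH301 at 96 probes, 9 higher and 87 lower, and from UH005 at 0. At an unadjusted p under 0.05 these counts were 547, 151, 467 and 191. Without replicates 1, 3 and 4 the count of 152 became 23, 41 and 62, and the count of 96 became 0 in each case. Without replicate 4 the comparison of 301x005 with UH301 gave 1 probe.

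In embryos of cross 301/005 limma called 0 probes for 301x005 and for 005x301 against either inbred. At an unadjusted p under 0.05 there were 308 and 273 against UH301 and 206 and 238 against UH005. Against UH301, 005x301 had 3 probes without replicate 1 and 1 without replicate 4. Against UH005, 301x005 had 1 without replicate 1 and 005x301 had 1 without replicate 3. In embryos of cross 301/250 it called 1 probe, for 301x250 against UH250, and 0 in the other comparisons, with 142 there, 115 for 250x301 against UH250, and 321 and 203 for 301x250 and 250x301 against UH301. In endosperm of that cross it called 0, with 47 and 52 against UH301 and 101 and 79 against UH250. FIE2 in 301/250 embryos measured -0.78 ± 0.41 in 301x250 against UH301 and -0.53 ± 0.29 against UH250, and in 250x301 -0.70 ± 0.31 and -0.16 ± 0.34 (SE, n = 2 loops). Without replicate 1 and without replicate 2 the embryo counts were 14 and 15 for 301x250 and 2 and 79 for 250x301 against UH301, and 8 and 2 for 301x250 and 6 and 1 for 250x301 against UH250. In endosperm 301x250 against UH250 had 10 and 250x301 against UH301 had 1 without replicate 2, and 250x301 against UH250 had 2 without replicate 1. The lone loop is then assumed to vary like the other groups.

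Whether tissues or crosses differed in these effects was tested as a contrast of coefficients. Between embryo and endosperm of cross 301/005, limma called 0 of 1697 probes for the mid-parent difference and 0 of 1789 for the reciprocal difference, with 89 and 176 at an unadjusted p under 0.05. Between crosses it called 0 of 1208 probes in embryos and 0 of 1832 in endosperm for the mid-parent difference, with 45 and 25. FIE2 and the other named genes are among the 0 in the tissue and cross contrasts in which they were tested.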

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

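The share of the inbred difference kept between reciprocal hybrids and all tests of explanations and of sign flips or splits given here were chosen after the results were seen.

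Hybrids of cross 301/005 lay nearer to their seed parent in endosperm, and the share differed from that in embryos by 0.84. Noise common to the reciprocal and inbred values of a loop is argued against. With the inbred difference taken from other loops the mean share was 0.633, above 0 by more than its SD of 0.21 and in each of the 4 loops. However, these shares are not independent, since each uses the inbred differences of the other loops. Sign flips of 4 loops also cannot give an exact p under 0.125. Whether genome dosage is the whole cause of the mean share stays open, since endosperm receives 2 maternal genomes to 1 paternal. With parental values adding on the linear scale, that gives a share of 0.333 for small inbred differences and less for large ones. The lowest loop's share, 0.395, and the other 3 lie above that value, and so do all loops with large values left out (mean 0.64). The plain slope lies at that value, at 0.33. Noise alone gave a covariance of -0.0377 between the 2 contrasts in the simulation, which would pull this slope down. The data do not show that pull. Contrasts from different loops had covariances of 0.108 and 0.119 (2732 probes), against 0.123 from the same loops (3227 probes). Noise in a loop's own inbred difference, which correlated with that of the other loops at r 0.41 to 0.64, also lowers a plain slope. How much either lowers it was not measured. The plain slope therefore cannot show that dosage suffices. Dosage is left open because 4 loops allow no exact sign flips p under 0.125 and the form of the share was chosen after the values were seen. Nearness to the seed parent rests on the naming convention. With the first-named line as pollen parent the share would turn negative and dosage could not be its cause. Maternal tissue carried over at dissection also stays open, since 0 named probes for nucellus and pericarp were on the array, and parental effects on expression such as imprinting remain untested.

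Control spots left out of all comparisons had large log ratios. In the deposited values MC4 had a median of -3.35 on the 24 arrays with the hybrid in channel 1 and 4.06 on the 24 with the hybrid in channel 2. MC5 had medians of 3.85 and -4.33, and each control had 1 sign on all arrays of an orientation. The empty-spot control ranged from -2.13 to 0.83 on the 301/250 arrays, with both signs where the hybrid was in channel 1. In 15 groups of 4 values, 0 had 1 far from the others by Dixon's criterion.

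Sign flips of the 4 loops number 8 per comparison, too few for a share under 0.05. For 301/005 the real inbred lists of 17 probes in embryos and 151 in endosperm and the real reciprocal list of 37 in endosperm compare with at most 0, 1 and 0 in the other flips, so 1 of 8 flips was as large. For the mid-parent difference and the hybrids outside both inbreds in both tissues, and for the reciprocal difference in embryos, the real count and the highest other were 0, so 8 of 8 were as large. With a real count of 0 that outcome was fixed beforehand and carries no information. For the differences between embryo and endosperm in the mid-parent and reciprocal effects, all 35 splits of the 8 loops gave as many probes (real 0, highest other 0), which was likewise fixed beforehand, so chance cannot be excluded for these.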

How the results depend on the processing

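The fits within 1 array version, the list tests against the P set, after scaling and over all comparisons, every alternative for the hybrids against single inbreds and the forms of the seed-parent share were chosen after results were seen. Of the main results, 227 values under the alternatives stayed within 1.5 times the main count and 76 moved. Many main results had no called probe, and a count that stayed empty also falls within that limit. The 227 values therefore do not show that lists with called probes were stable. In 301/005 the inbred lists of 17 and 151 probes and the reciprocal list of 37 each moved under several alternatives. So did the reciprocal list of 4 in 301/250 embryos. Of the values for named genes and the seed-parent share, 541 stayed the same, which for genes means direction and side of the threshold. A further 11 reversed, 8 passed only under the alternative, 1 passed only in the main setting, and 1, the share, moved. As no named gene passed for the mid-parent, reciprocal or inbred difference, keeping the side of the threshold was nearly given. The cause was not tested except where stated.

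Fits of single arrays treat arrays that share RNA as nearly independent, which by construction raises counts. With the replicate block and without it they called 1 and 17 probes for the mid-parent difference in 301/005 embryos, 3 and 28 in 301/005 endosperm, and without it 1 in 301/250 endosperm. For the reciprocal difference they called 6 and 4 in 301/005 embryos, 92 and 79 in 301/005 endosperm (main 37), and 25 and 8 in 301/250 embryos (main 4). For the inbred difference they called 101 and 77 (main 17), 324 and 270 (main 151), 11 and 4, and 5 and 4 in the 301/005 embryo, 301/005 endosperm, 301/250 embryo and 301/250 endosperm. In them WEE1 (mid-parent -0.42), NFD106 (reciprocal 1.14, inbred -1.02) in 301/005 embryos and HSP101 (inbred -0.35) in 301/005 endosperm passed, and DMT106 in 301/005 embryos turned to -0.0384 and -0.0165 for the mid-parent and 0.00631 for the reciprocal difference.

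A spread from the compared loops alone, with few degrees of freedom, gave 0 probes for the reciprocal difference in 301/005 endosperm and 301/250 embryos and for the inbred difference in both 301/005 tissues, and 1 for the mid-parent difference in 301/005 endosperm. It could not be run for the mid-parent difference of 301/250, which has no residual degrees of freedom. Scaling gave 0 for the reciprocal difference in 301/250 embryos, 55 for the inbred difference in 301/005 endosperm and 4 in 301/250 endosperm. Probes on all arrays, fewer tests by construction, gave 1 for the mid-parent difference in 301/250 embryos, 6 and 26 for the reciprocal difference in 301/005 endosperm and 301/250 embryos, and 7 for the inbred difference in 301/005 endosperm. Within the loops of either array version the inbred difference in 301/005 embryos gave 0. Without a dye coefficient 005x301 against UH301 in embryos gave 2. Of the 12 list tests, 5 passed in the main setting, 1 with an estimated correlation, 3 after centring, 2 after scaling and 0 when adjusted over all comparisons. Against the P set 2 passed, and the 301/005 embryo comparisons could not be tested that way. The plain slope moved the 301/005 endosperm share to 0.33. The fry test was not run.

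Embryo and endosperm loops share numbers, but same-numbered loops correlated at 1.1e-05, 0.23, 0.28 and 0.49 in the mid-parent, -0.01, 0.03, 0.02 and -0.06 in the reciprocal and 0.06, 0.25, 0.09 and 0.12 in the inbred difference, and not every loop correlated best with its own number, so they were not taken as pairs. With the replicate block the tissue difference of the reciprocal effect had 1 probe against 0.

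Leaving out each replicate gave 4 to 52 probes for the reciprocal difference in 301/005 endosperm, 3 to 10 in 301/250 embryos and 0 to 2 in 301/250 endosperm. For the inbred difference it gave 1 to 11 in 301/005 embryos, 42 to 82 in 301/005 endosperm and 0 to 3 in 301/250 embryos. In 301/005 endosperm the range was 0 to 1 for 301x005 and 0 to 118 for 005x301 against UH301, and 23 to 119 for 301x005 against UH005. In 301/005 embryos it was 0 to 3 for 005x301 against UH301 and 0 to 1 for each hybrid against UH005. In 301/250 embryos it was 14 to 15 and 2 to 79 for 301x250 and 250x301 against UH301, and 2 to 8 and 1 to 6 against UH250. In 301/250 endosperm it was 0 to 1 for 250x301 against UH301, and 0 to 10 and 0 to 2 against UH250. Where too few loops or degrees of freedom remained it was not run for single genes, among them 301/250 NFC103 (mid-parent), SGB101 (inbred, embryos) and MBD113 (inbred, endosperm) and EF1A (inbred, 301/005 embryos), whose loops had opposite signs. Where run, values that reversed were GAPDH in 301/250 (mid-parent in endosperm -0.0517 to 0.26, inbred in embryos -0.66 to 0.0511) and DMT106 in 301/005 embryos (reciprocal -0.14 to 0.0155). MET1 and FIE2 reversed in 301/250 endosperm (reciprocal -0.0785 to 0.42 and -0.15 to 0.76), as did FIE2 in 301/005 endosperm (inbred -0.18 to 0.36) and GLN4 in 301/250 embryos (inbred -1.48 to 0.19). No signal over background was at hand, so its limit on the ratios is unknown.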

Other observations

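All gene families, shared-sign counts and tests in this part were chosen after values had been seen.

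The 50 probes of chromatin genes, taken as 1 group, were mostly below the mid-parent in 301/005 endosperm (19 of 24 measured, median -0.13) and in 301/250 embryos (15 of 20, median -0.10), with camera adjusted p of 0.00322 and 0.0153. With an estimated correlation the adjusted p was 0.0566 and 0.0659, and against other probes of the P set 0.0266 and 0.303. The genes with the lowest p were FIE2, GTE102 and NFD106 in the first group and FIE2, NFA102 and BRD103 in the second. In 301/250 endosperm 17 of 24 were below it (adjusted p = 0.213), and in 301/005 embryos 8 of 11 were above it (adjusted p = 0.408). After scaling the adjusted p in 301/250 embryos was 0.0574, so that call was lost, and the medians kept their signs after centring and scaling. Differences of the group between tissues or crosses were not tested.

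Between reciprocal hybrids, 10 of 11 chromatin probes, 2 of them for the gene of MET1 and DMT101, were higher in 301x005 embryos (median 0.18, adjusted p = 0.00553, and 0.0345 with an estimated correlation), while 19 of 26 were lower in 301x250 embryos (median -0.26, adjusted p = 0.00377, and 0.0344 with an estimated correlation). The second call was lost against probes of the P set (adjusted p = 0.447), whose own median was -0.16 there against 0.08 for other probes. Between the 301/005 inbreds 10 of these 11 probes were lower in UH301 embryos (median -0.30, adjusted p = 0.00157, and 0.0107 with an estimated correlation), which comes from the same arrays, with the largest values in replicate 4, and is not a separate finding. The 301/005 embryo values of probes of the P set rest on replicates 3 and 4 alone. In 301/250 endosperm 20 of 31 were lower in 301x250 (median -0.07, adjusted p = 0.0152, and 0.0668 with an estimated correlation). Among them 4 of 5 methyl-CpG-binding domain genes were lower, led by MBD106 (median -0.10, adjusted p = 0.023, and 0.0403 with an estimated correlation). Of 18 family tests 7 passed, against 4 with an estimated correlation and 6 after scaling.

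Probes called between the inbreds in 301/005 endosperm mostly kept their sign elsewhere. In 301/005 embryos 90 of 102 had the same sign, against 58.7% of all probes, with a median difference of 0.46 in that sign against 1.23 in endosperm. In the difference of UH301 from UH250, where no probe passed, the sign was the same for 132 of 135 in endosperm (66.6% of all probes, median 0.49 against 1.37) and 45 of 61 in embryos (54.0% of all probes, median 0.20 against 1.17). Both differences contain UH301, and whether its RNA came from the same plants in both crosses is not given in the sources used here, so they are not independent and shared signs can arise from UH301 alone.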
